A study of Mus musculus with 12 samples.

How the data were processed

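Total RNA from the livers of 12 mice was measured on whole-transcript arrays, 1 array per mouse. Per the labels' protocols, the RNA was extracted with Trizol from livers that were flash frozen 24 h after the last dose, and biotin-labelled sense-strand target was made for Affymetrix arrays. The mice belonged to 3 groups of 4, each with 2 males and 2 females. One group received water, 1 received silver particles coated with citrate, and 1 received silver particles coated with polyvinylpyrrolidone (PVP). The arrays were grouped by the treatment and sex in the labels.

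The deposited table held log2 signal values, with RMA (robust multi-array average) and Transcriptome Analysis Console 4.0.1.36 named in the submitters' processing notes without their roles or order. It covered 72688 probe sets, and its values ran from 1.73 to a ceiling of 19.93 without centring per gene. The medians of the arrays lay between 4.13 and 4.40. Because the table has a ceiling, changes of the most abundant transcripts could be understated, and 208 probe sets were at the ceiling on at least 1 array. The genome build and the annotation behind the signals were not given in the sources used here. Scanner intensities were not used here. No adjustment was made before the tests.

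Probe sets were named from the platform's own table, in which 30604 named exactly 1 gene symbol, 2146 named several and 39938 named none; 6732 of the probe sets were array controls. Symbols were brought up to date for 1135 probe sets with a RefSeq gene table of the GRCm38.p6 assembly, which was used only for names, gene types and chromosomes. Among the probe sets that named 1 symbol, the probe set with the highest mean over the 12 arrays stood for its gene, which mattered for 429 genes. Of 30063 genes, the 19985 whose mean lay above the 40th percentile of all probe sets, a log2 signal of 3.93, were tested.

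Differences were tested with limma 3.58.1 in R 4.3.3, with the spread moderated along the mean signal. A single fit to the 12 arrays with a term for each group and for sex gave both coatings against control, PVP against citrate, and female against male. A fit with 6 means of group by sex gave the effect of each coating in females minus its effect in males, and the effects within each sex, from 2 mice per mean. The tests were two-sided, and p-values were adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05. Log2 fold changes are given with the standard error (SE) of the fit, and group levels as mean ± standard deviation (SD).

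Of 48 gene lists of metabolic, stress, inflammatory and repair pathways and of cell types, 46 had at least 5 tested members; 957 of their 1094 distinct genes had a probe set of 1 symbol. The lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists within each comparison. An estimated correlation and fry, which asks whether the members move on balance one way without comparing them with other genes, were run beside it. The mixed test of fry and the median deviation of a list's members in each mouse from the control mean of the same sex were taken up after the data were seen. For each list the members were also counted when adjusted over the list alone. The model, the filter, the gene lists, the rule for naming genes and most alternatives were chosen before the data were examined.

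The genes named for each comparison between groups were the 12 with the largest rise and the 12 with the largest fall among those past the threshold with the same sign in both sexes. Where fewer than 20 genes passed, genes of the smallest p were added up to 20 and are given as not having passed. Up to 4 members per list that passed over all genes or over the list alone were added, or the 4 of smallest p where the list passed as a set without such a member. A further 24 genes of metal handling, oxidative stress, drug metabolism, inflammation and other liver functions were fixed whatever their result, and 21 of them were tested. For sex, the 5 largest changes each way and 5 genes linked to the X or Y chromosome were taken, and for each difference between the sexes in response the 5 genes of smallest p. Predicted genes were counted and are named only where stated, and some genes that the rule gives are left out. Lpin1 and Zbtb16 in PVP-treated mice, some metallothionein, acute phase and lipid genes in other comparisons, and the 3 predicted genes were added after their values were seen.

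The fold changes of both coatings share 4 control mice, so their correlation was set against 100 simulations of unchanged groups and against fold changes from controls split into separate pairs. Array quality was summarised as the area under the receiver operating characteristic (ROC) curve that separates 1324 exon control probe sets from 5222 intron control probe sets; groups were compared on it with exact permutation tests. The tests were also tried on simulated data with 200 changed genes, a shifted list and noise drawn independently for each gene. Structure shared by the genes of an array was left out, so the shares that follow need not hold for the real arrays. With PVP against control, 84 of 100 simulated genes changed by 1 on the log2 scale were recovered with the right sign, as were 99 of 100 changed by 2, while 14 of 19769 unchanged genes were called.

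Alternatives changed 1 choice at a time, save that an unadjusted p under 0.05 was combined with a fold cut of 1.5. They covered the level filter, the choice of probe set, centring, quantile normalization, the spread model, array weights, the sex term, the arrays in the fit, the threshold, a leading component of the residuals and each array left out in turn. Array quality as a covariate, the fit without the 2 arrays of lowest quality, the restriction to protein-coding genes and the counts of list members under these settings were added after the data were seen. Other splits of the same arrays were tested for each count between groups of at least 4 arrays, and again over the splits that balance sex and over the largest count of any list, which were added after the data were seen. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for naming, quality measures and figures. For arrays, their number limits the precision.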

Results

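Hepatic gene expression was measured in 12 mice of the strain C57BL/6J -Oca2p-un/J, which carries the pink-eyed unstable allele of the Oca2 gene. The mice were 3 months old. Silver nanoparticles of 20 nm, coated with citrate or with polyvinylpyrrolidone (PVP), were given by oral gavage at 4 mg of silver per kg in 7 daily doses, and water was given to the control mice. Citrate is a small, charged molecule that stabilises particles by repulsion, and PVP is a neutral polymer that stabilises them sterically. Each of the 3 groups held 4 mice, 2 of each sex, with 1 array per mouse. The number of arrays limits the precision of every value below.

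The arrays differed in quality. The area under the ROC curve for exon over intron control probe sets was 0.824 ± 0.016 in control livers, 0.820 ± 0.00624 in citrate-treated livers and 0.802 ± 0.0198 in PVP-treated livers (mean ± SD, n = 4 each). PVP replicates 1 and 4 had the lowest areas of the 12 arrays, 0.778 and 0.794, against 0.804 to 0.842 on the others. The difference of -0.0219 between PVP and control did not pass (exact permutation test, two-sided p = 0.171), nor did that of -0.0183 between PVP and citrate (exact permutation test, two-sided p = 0.143). PVP replicate 1 also had the highest array median, 4.401 against at most 4.28 on the others. The sexes in the labels matched the arrays. Xist, the RNA that silences an X chromosome in females, had log2 signals of 15.60 to 16.60 in the 6 females and 4.77 to 7.16 in the males, and the Y-linked translation factor gene Eif2s3y had 4.74 to 5.18 in females and 9.06 to 9.49 in males.

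**Figure D1:**
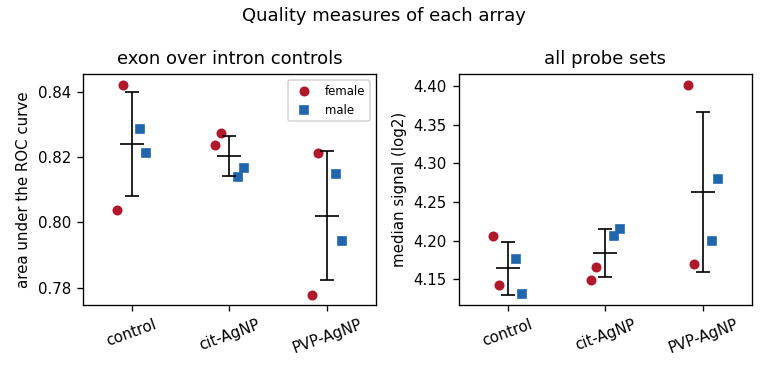
Area under the ROC curve of exon over intron control probe sets (left) and median log2 signal of all probe sets (right) for each array by group, with circles for females, squares for males and bars for mean ± SD (n = 4). PVP replicate 1 has the lowest area, 0.778, and the highest median, 4.401.

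The comparison of citrate-coated particles with water asked which liver genes respond to this coating. Grb7, an adaptor protein of receptor tyrosine kinases encoded on chromosome 11, fell by 1.00 on the log2 scale (SE 0.10, limma adjusted p = 0.0182). Its level was 9.61 ± 0.23 in control livers and 8.61 ± 0.17 in citrate-treated livers (log2, mean ± SD, n = 4 each). Each of the 4 exposed livers lay below each of the 4 control livers. Among the genes of small p that did not pass, Bcar3, a signalling adaptor, had a log2 fold change of -1.01 (SE 0.12), and Camsap3, which binds microtubule minus ends, -0.48 (SE 0.06), each with an adjusted p of 0.052. Tns2, Tnfaip2 and Irak2 had values of -0.99, -0.64 and -0.66, with adjusted p-values of 0.095, 0.0944 and 0.0944. Lurap1l had +1.02 (SE 0.16, adjusted p = 0.122). Of 19985 genes tested with limma, 0 were higher and 1 was lower with citrate. At an unadjusted p under 0.05 there were 1313 genes, 549 higher and 764 lower, where chance would give 999 on average. Genes of an array share structure, so counts by chance can lie far from 999, and their spread was not computed. The count was 0 without control replicate 1, 2 or 3, citrate replicate 1, 2 or 4, or PVP replicate 4, and 6 without PVP replicate 1. The call of Grb7 was lost without control replicate 1, 2 or 3, any of citrate replicates 1 to 4, or PVP replicate 4, with adjusted p-values of 0.0697 to 0.179.

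Glucocorticoid-responsive genes were shifted higher as a set with citrate, with 14 of 17 members above 0 (camera adjusted p = 0.000263; adjusted p = 0.967 with an estimated correlation). Of these members 1 rose, adjusted over the list alone, and 0 passed over all genes in limma, with 6 at an unadjusted p under 0.05. That member was Zbtb16, a glucocorticoid-induced transcription factor, whose log2 fold change was 2.38 (SE 0.41, adjusted p over all genes 0.144), from 6.07 ± 0.19 to 8.44 ± 0.87 (log2, mean ± SD, n = 4 each). In PVP-treated mice it stood at 6.87 ± 0.66. Without PVP replicate 1 the list had 5 members past its own adjustment, without PVP replicate 4 it had 6, and without citrate replicate 3 it had 2. Other lists held the genes that follow. The fatty acid synthesis list did not pass (camera adjusted p = 0.781) and had 1 member that rose and 1 that fell over the list alone. The phosphatidate phosphatase gene Lpin1 had a value of 3.57 (SE 0.86, adjusted p = 0.316), from 11.60 ± 0.99 to 15.17 ± 0.74, against 11.86 ± 1.87 with PVP, and Mlxipl, which encodes the glucose-sensing factor ChREBP, -0.98 (SE 0.23, adjusted p = 0.296). Igfbp1, an insulin-repressed binding protein of the gluconeogenesis list, had 3.02 (SE 1.15, adjusted p = 0.628), and the transcription factor Cebpb, of the acute phase list, 0.54 (SE 0.15, adjusted p = 0.409).

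Acute phase genes were shifted higher with citrate as a set, with 22 of 27 members above 0 and a median log2 fold change of 0.41 (camera adjusted p = 0.000117). The list holds plasma proteins of the liver's inflammatory response and also other genes. Its 4 members of smallest p with citrate were such genes, the transcription factors Cebpb and Cebpd, the metallothionein Mt2 and the receptor Il1r1. Citrate replicate 1, a female, stood apart: the median deviation of the members from the control mean of the same sex was 0.82 in this liver and 0.03, 0.07 and 0.27 in replicates 2 to 4. The call was kept in each of the 12 fits with an array left out, with adjusted p-values of at most 0.0168. Saa1, a serum amyloid A gene, had 1.56 (SE 1.23, adjusted p = 0.955), and Il1r1, an interleukin-1 receptor, 1.68 (SE 0.64). Targets of NRF2 and genes of glutathione metabolism were shifted lower, with 23 of 26 members below 0 (camera adjusted p = 6.65e-05). Nfe2l2, which encodes NRF2, had -0.73 (SE 0.20, adjusted p = 0.399) and Nqo1, a quinone reductase, -0.52 (SE 0.19, adjusted p = 0.59). Neither list had a member past the threshold over the list alone or over all genes in limma, with 5 members of each at an unadjusted p under 0.05. Both calls were lost with an estimated correlation (adjusted p = 0.967).

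Cholesterol biosynthesis genes were shifted higher, with 17 of 19 members above 0 (camera adjusted p = 0.00266), among them Sqle at 1.46 (SE 0.58) and Dhcr7 at 0.66 (SE 0.25). Kupffer cell and macrophage markers were shifted higher, 19 of 19 above 0 (camera adjusted p = 0.000879), with Cd163, a haemoglobin scavenger receptor, at 0.96 (SE 0.41). PPAR-alpha targets and genes of fatty acid oxidation were shifted lower, 25 of 30 below 0 (camera adjusted p = 0.00439), with Plin2, a lipid droplet coat protein, at -0.76 (SE 0.21). Stellate cell markers (camera adjusted p = 0.00439) and circadian clock genes (camera adjusted p = 0.0245) were shifted lower. Of the clock genes, the repressor Nr1d1 fell when adjusted over the list alone (-1.23, SE 0.23, adjusted p over all genes 0.187). Genes of gluconeogenesis and fasting were shifted higher (camera adjusted p = 0.0451). Of these 6 lists, only the clock had a member past the list alone, and 0 members passed over all genes in limma. Each of the 9 lists called had an adjusted p of 0.967 with an estimated correlation. Calls were lost without control replicate 2 for cholesterol biosynthesis (0.155) and Kupffer cells (0.369), and without control replicate 3 or 4 for stellate cells (0.106 and 0.174). They were lost without control replicate 4 or citrate replicate 3 for the clock (0.207 and 0.214) and PPAR-alpha targets (0.812 and 0.214). For gluconeogenesis the call was lost without control replicate 1 or 2, citrate replicate 2 or 4, or PVP replicate 2 or 3 (0.0545 to 0.473). The clock list had 2 members past its own adjustment without PVP replicate 1, 3 or 4.

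The comparison of PVP-coated particles with water gave 8 genes past the threshold, and 0 without the 2 arrays of lowest exon over intron area. Snord16a, a small nucleolar RNA that guides ribosomal RNA methylation and lies on chromosome 9, rose by 1.09 (log2, SE 0.09, adjusted p = 0.0049), from 15.68 ± 0.36 in control livers to 16.77 ± 0.48 in PVP-treated livers (mean ± SD, n = 4 each). Gstk1, a mitochondrial and peroxisomal glutathione transferase on chromosome 6, fell by 0.97 (SE 0.13, adjusted p = 0.046), from 14.67 ± 0.20 to 13.70 ± 0.24. Grb7 fell by 0.89 (SE 0.10, adjusted p = 0.0178), and Camsap3 fell by 0.48 (SE 0.06, adjusted p = 0.0341). Anp32-ps, a pseudogene, fell by 1.13 (SE 0.14, adjusted p = 0.0341), from 12.65 ± 0.19 to 11.52 ± 0.17. In the 4 genes that fell, each PVP-treated liver lay below each control liver, and Snord16a was higher in each PVP-treated liver than in each control liver. The 3 other genes had predicted names, of which Gm20300, a long noncoding RNA, fell by 0.98 (adjusted p = 0.0178), while the pseudogenes Gm4910 and Gm20871 rose by 0.77 and 0.54 (adjusted p = 0.046 for each). Small nucleolar RNAs, the class of Snord16a, had array medians of 4.69, 4.20, 4.41 and 4.53 in PVP replicates 1 to 4. In control replicates 1 to 4 these were 4.31, 4.32, 4.20 and 4.20, and the difference was not tested. Small nuclear RNAs, another class, had a median signal 0.362 higher in PVP-treated than in control livers, which did not pass (exact permutation test, two-sided p = 0.143).

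Of the 19985 genes tested, 3 were higher and 5 lower with PVP. At an adjusted p under 0.1 there were 272. At an unadjusted p under 0.05 there were 4057, 1609 higher and 2448 lower, where chance would give 999 on average. The spread of that number by chance was not computed, so the excess alone does not establish a broad response. The count moved with the arrays in the fit. It was 3 without control replicate 1, 14 without control replicate 2, 5 without citrate replicate 4, 61 without PVP replicate 3, and 1 without control replicate 3 or 4, citrate replicate 1, 2 or 3, or PVP replicate 1 or 4. With the exon over intron area as a covariate the count was 2. It was 0 without the 2 arrays of lowest area, in a fit to 2 groups only and with 6 means of group by sex. The call of Snord16a was lost in those fits with 0 genes and kept in each of the 12 fits with an array left out. Of the other calls, those of Grb7, Camsap3 and Anp32-ps were kept in 4 and that of Gstk1 in 2. That of Gm20300 was kept in 5, that of Gm20871 in 2 and that of Gm4910 in 1, with adjusted p-values of at most 0.134 where lost. The calls of Grb7, Camsap3 and Anp32-ps were each lost without control replicate 1, 3 or 4, citrate replicate 1, 2 or 3, or PVP replicate 1 or 4, and those of Gstk1 and Gm20871 also without citrate replicate 4 or PVP replicate 2. That of Gm20300 was lost without control replicate 3 or 4, citrate replicate 1, 2 or 3, or PVP replicate 1 or 4, and that of Gm4910 without each array other than PVP replicate 3.

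Heat shock response genes were shifted lower with PVP as a set (camera adjusted p = 4.33e-05; adjusted p = 0.79 with an estimated correlation). Of 16 members, 8 fell when adjusted over the list alone and 0 passed over all genes in limma, with 9 at an unadjusted p under 0.05. Hsp90aa1, the inducible cytosolic HSP90 chaperone, had a log2 fold change of -1.21 (SE 0.20, adjusted p over all genes 0.0577), from 13.31 ± 0.25 in control livers to 12.09 ± 0.30 in PVP-treated livers, against 13.29 ± 0.33 with citrate (log2, mean ± SD, n = 4 each). The HSP110 chaperone Hsph1 had -1.41 (SE 0.21, adjusted p = 0.0566), the HSP70 to HSP90 adaptor Stip1 -1.39 (SE 0.23, adjusted p = 0.0577), and the HSP90 ATPase activator Ahsa1 -0.61 (SE 0.11, adjusted p = 0.0675). In each of these 4 genes, each PVP-treated liver lay below each control liver. The median deviation of the members from the control mean of the same sex was -0.50, -0.35, -0.32 and -0.22 in PVP replicates 1 to 4 and -0.14 to 0.14 in controls. Each control was part of the mean of 2 mice that it was set against, which narrows the control range. The 2 ranges are therefore not directly comparable. The count of members was 5 without control replicate 4 and 6 to 9 without any other single array. The exon over intron area was also lower on the PVP arrays, 0.802 ± 0.0198 against 0.824 ± 0.016 in controls. PVP replicate 1, with the lowest area, had the largest fall, and PVP replicate 4, with the next lowest, the smallest. With that area as a covariate 5 members passed, and without the 2 arrays of lowest area 6 did.

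**Figure D2:**
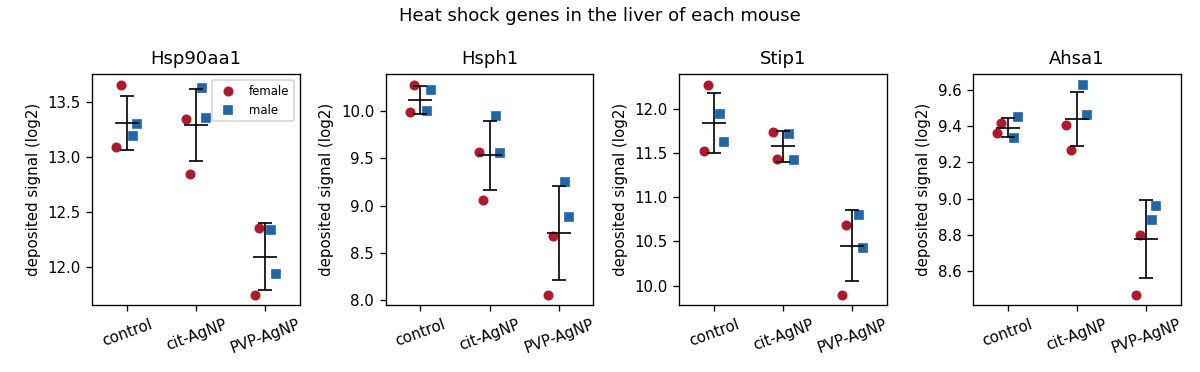
Log2 signal of Hsp90aa1, Hsph1, Stip1 and Ahsa1 in each liver by group, with circles for females, squares for males and bars for mean ± SD (n = 4). For Hsp90aa1 the PVP-treated livers lie between 11.75 and 12.35, below the citrate-treated livers at 12.84 to 13.63 and the controls at 13.09 to 13.65.

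Acute phase genes were shifted higher with PVP, with 24 of 27 members above 0 and a median log2 fold change of 0.82 (camera adjusted p = 1.32e-09; adjusted p = 0.79 with an estimated correlation). PVP replicate 2, a female, stood apart, with a median deviation of the members from the control mean of the same sex of 1.57, against 0.78 in replicate 1 and 0.19 and 0.38 in the males, replicates 3 and 4. Of the 27, 14 rose when adjusted over the list alone and 0 passed over all genes in limma, with 16 at an unadjusted p under 0.05. The serum amyloid gene Saa2 had 6.80 (SE 1.34, adjusted p over all genes 0.0757), from 9.13 ± 1.21 in control livers to 15.93 ± 3.95 in PVP-treated livers (log2, mean ± SD, n = 4 each). Saa1 had 5.83 (SE 1.23, adjusted p = 0.0877), from 10.49 ± 1.06 to 16.31 ± 3.16. Orm1, an alpha-1-acid glycoprotein, had 1.00 (SE 0.26, adjusted p = 0.123), Itih4 0.66 (SE 0.17, adjusted p = 0.126), and Lcn2, an iron-withholding lipocalin, 3.94 (SE 1.07, adjusted p = 0.128). Without control replicate 2 or 4 or PVP replicate 2 the count of members fell to 2, and without PVP replicate 1 it was 7. The PVP arrays also had lower exon over intron areas, 0.802 ± 0.0198 against 0.824 ± 0.016; 12 members passed with the area as a covariate and 7 without the 2 arrays of lowest area.

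**Figure D3:**
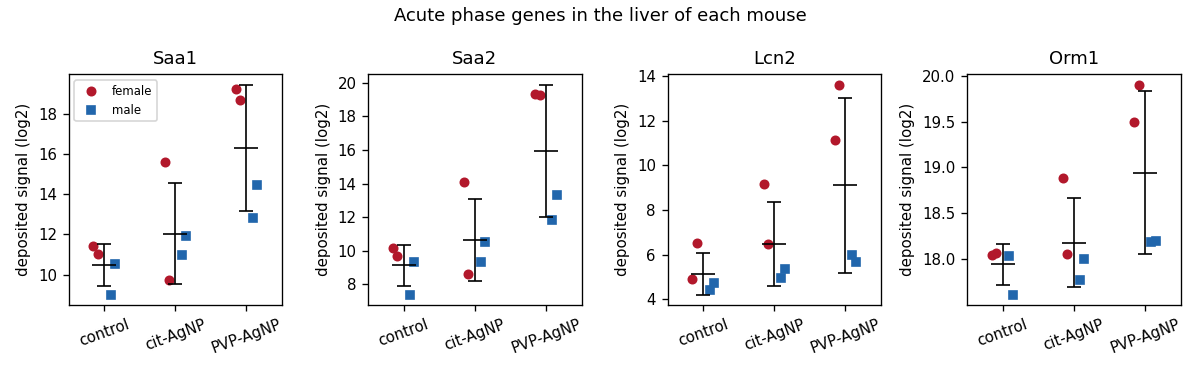
Log2 signal of Saa1, Saa2, Lcn2 and Orm1 in each liver by group, with circles for females, squares for males and bars for mean ± SD (n = 4). The Saa1 signals of the PVP-treated females are 18.70 and 19.26 and those of the PVP-treated males 12.84 and 14.46, against at most 11.41 in controls.

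Targets of NRF2 and genes of glutathione metabolism were shifted lower with PVP, with 24 of 26 members below 0 (camera adjusted p = 2.64e-07; adjusted p = 0.79 with an estimated correlation). Of these, 10 fell when adjusted over the list alone and 0 passed over all genes in limma, with 15 at an unadjusted p under 0.05, 14 lower and 1 higher. The glutathione transferases Gstm3, Gstm4 and Gstm2 had log2 fold changes of -1.58 (SE 0.27, adjusted p over all genes 0.0629), -0.84 (SE 0.14, adjusted p = 0.0577) and -0.73 (SE 0.14, adjusted p = 0.0707), and Gsta4, which conjugates lipid aldehydes, had -1.14 (SE 0.29, adjusted p = 0.119). Antioxidant enzymes were shifted lower (camera adjusted p = 0.0251; adjusted p = 0.843 with an estimated correlation), with 3 of 23 past the list alone. They were the peroxiredoxins Prdx2 (-0.40, SE 0.09) and Prdx3 (-0.73, SE 0.19) and the mitochondrial thioredoxin Txn2 (-0.51, SE 0.13). The median deviation of the glutathione members from the control mean of the same sex was -0.93 and -0.74 in the PVP-treated females and -0.11 and -0.48 in the males, replicates 3 and 4. The glutathione count was 3 without control replicate 2, 5 without PVP replicate 1 and 17 without PVP replicate 3. The antioxidant count was 0 without control replicate 3 or 4 or PVP replicate 1 or 4 and 6 without PVP replicate 3, and its set call was lost without PVP replicate 1 (0.117) or 4 (0.0515). With the exon over intron area as a covariate, 5 glutathione members and 1 antioxidant member passed, and without the 2 arrays of lowest area 6 and 0 did.

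Of the metabolic lists, 3 lists were shifted lower with PVP, while cholesterol biosynthesis (0.817), gluconeogenesis and fasting (0.935) and bile acid synthesis and transport (0.387) did not pass in camera. Among nuclear genes of oxidative phosphorylation, 34 of 38 lay below 0 (camera adjusted p = 3.4e-07; adjusted p = 0.834 with an estimated correlation). When adjusted over the list alone 16 fell, such as the complex III core subunits Uqcrc1 (-0.61, SE 0.15, adjusted p over all genes 0.117) and Uqcrc2 (-0.66, SE 0.17, adjusted p = 0.119). Fatty acid synthesis genes had 20 of 21 below 0 (camera adjusted p = 1.55e-05; adjusted p = 0.79 with an estimated correlation) and 8 that fell over the list alone. Among them were the elongase Elovl5 (-1.03, SE 0.20, adjusted p = 0.073), Mlxipl (-0.86, SE 0.23, adjusted p = 0.125), and its target Txnip (-1.81, SE 0.45, adjusted p = 0.117). PPAR-alpha targets had 29 of 30 below 0 (camera adjusted p = 1.55e-05; adjusted p = 0.843 with an estimated correlation) and 3 that fell over the list alone. These were Ehhadh, a peroxisomal beta-oxidation enzyme (-1.52, SE 0.23, adjusted p = 0.0566), Plin2 (-0.96, SE 0.21, adjusted p = 0.0952) and Cpt2, a mitochondrial carnitine palmitoyltransferase (-0.99, SE 0.26, adjusted p = 0.126). Over all genes 0 members of these lists passed in limma; at an unadjusted p under 0.05 there were 19, 9 and 8. The oxidative phosphorylation count was 0 without control replicate 3 or 4 or PVP replicate 1, 2 or 4, 9 without control replicate 2 and 10 without citrate replicate 3. The fatty acid synthesis count was 5 without control replicate 2, 1 without control replicate 3 or PVP replicate 1, 2 without PVP replicate 2, 4 without control replicate 4 or citrate replicate 2, and 3 without citrate replicate 1 or 4. The PPAR-alpha count was 11 without control replicate 2, 8 without PVP replicate 3, and 1 without control replicate 3 or 4 or PVP replicate 1 or 4. Beside the lower exon over intron area of the PVP arrays, these counts were 0, 3 and 3 where the area was a covariate and 0, 2 and 1 without the 2 arrays of lowest area.

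Some lists of cell type markers and that of complement passed with PVP at the preset correlation, and 0 passed with an estimated correlation. Endothelial markers were shifted lower (camera adjusted p = 0.00472; adjusted p = 0.843 with an estimated correlation). Of 19, 5 fell when adjusted over the list alone, including Gpr182, a receptor of sinusoidal endothelium (-0.58, SE 0.11, adjusted p over all genes 0.0683), Eng, a TGF-beta co-receptor (-0.70, SE 0.17, adjusted p = 0.114), and Oit3 (-0.74, SE 0.19, adjusted p = 0.125). Stellate cell and fibroblast markers had 17 of 17 below 0 (camera adjusted p = 0.000784; adjusted p = 0.834 with an estimated correlation). Those that fell over the list alone numbered 3, the extracellular glycoprotein gene Reln (-0.83, SE 0.16, adjusted p = 0.071), the proteoglycan gene Bgn (-0.90, SE 0.18, adjusted p = 0.0819) and the PDGF receptor gene Pdgfrb (-0.38, SE 0.09, adjusted p = 0.104). Kupffer cell markers had 19 of 19 above 0 (camera adjusted p = 0.00322), with the macrophage-secreted Cd5l at 10.62 ± 0.40 in control livers and 11.98 ± 1.20 in PVP-treated livers (mean ± SD, n = 4 each; limma adjusted p = 0.168). Monocyte and neutrophil markers had 13 of 16 above 0 (camera adjusted p = 0.00485), with the calprotectin genes S100a8 at 2.10 (SE 0.74) and S100a9 at 1.96 (SE 0.72). Complement and coagulation genes were shifted higher (camera adjusted p = 0.0182; adjusted p = 0.852 with an estimated correlation), with Hc, complement C5, at 0.98 (SE 0.25) and C4b at 1.35 (SE 0.36). Skeletal muscle markers were shifted higher too (camera adjusted p = 0.0278). The Kupffer, monocyte, complement and muscle lists had 0 members past the list alone, with 3, 4, 6 and 1 higher and 2 complement genes lower at an unadjusted p under 0.05. Over all genes 0 members of the 6 lists passed in limma. The Kupffer, monocyte and muscle calls had an adjusted p of 0.843 with an estimated correlation. The endothelial count was 1 without control replicate 3 or 4 or PVP replicate 1, and its call was lost without PVP replicate 1 (0.0725). The stellate count was 5 without control replicate 2 or PVP replicate 2. The Kupffer call (0.274 and 0.323) and the monocyte call (0.0572 and 0.145) were lost without control replicate 2 or PVP replicate 2. The complement call was lost without control replicate 2 or 4 or PVP replicate 2 (0.0541, 0.0635 and 0.544), and the muscle call without control replicate 3 or 4 or PVP replicate 1 or 4 (0.0569 to 0.171). Beside the lower exon over intron area of the PVP arrays, 0 endothelial and 4 stellate members passed with the area as a covariate, and 0 and 3 without the 2 arrays of lowest area.

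Metal response and DNA damage were examined with lists and fixed genes. Mt1 and Mt2, metallothioneins that bind silver, zinc and copper, were not past the threshold in either comparison with control. With citrate, Mt1 had a log2 fold change of 3.00 (SE 1.17, limma adjusted p = 0.647) and Mt2 3.95 (SE 1.42, adjusted p = 0.59); with PVP, Mt1 had 2.49 (SE 1.17, adjusted p = 0.262) and Mt2 3.49 (SE 1.42, adjusted p = 0.211). These values average the sexes. With citrate, Mt1 had 0.44 in females and 5.56 in males and Mt2 0.79 and 7.10; with PVP, Mt1 had 0.42 and 4.56 and Mt2 0.86 and 6.13. The 4 exposed females read 17.34 to 17.37 for Mt1, where a saturated signal was not ruled out. The Mt1 signals of the 4 control livers ranged from 8.86 to 16.98. The metal response list, 18 members, did not pass as a set (camera adjusted p = 0.847 with citrate and 0.797 with PVP). Its median log2 fold change was -0.03 with citrate and -0.08 with PVP, and its mean 0.33 and 0.22, opposite in sign. Hmox1, the inducible haem oxygenase, had 0.18 (SE 0.26, adjusted p = 1) with citrate and 0.68 (SE 0.26, adjusted p = 0.205) with PVP. Cdkn1a, the p53 target that encodes the cell cycle inhibitor p21, had 0.81 (SE 0.31, adjusted p = 0.626) with citrate and -0.02 (SE 0.31, adjusted p = 0.979) with PVP, a value that was above 0 without control replicate 2 (0.03) or 4 (0.05) or PVP replicate 1 (0.36). Ogg1, a glycosylase that removes oxidised guanine, had -0.19 (SE 0.09, adjusted p = 0.775) with citrate and -0.08 (SE 0.09, adjusted p = 0.592) with PVP. The list of p53 targets did not pass (camera adjusted p = 0.673 with citrate and 0.809 with PVP), nor did base excision repair (0.146 and 0.727), double-strand break repair (0.292 and 0.176) or nucleotide excision and mismatch repair (0.366 and 0.0707). The mixed test of fry, which asks whether members change in either direction without comparing them with other genes, passed with PVP in 17 of 46 lists and with citrate in 0. With PVP these 5 lists were among the 17, metal response (adjusted p = 0.00998), p53 targets (0.00998), base excision repair (0.0064), double-strand break repair (0.0267) and nucleotide excision and mismatch repair (0.0101). Over all 19985 genes, 4057 were at an unadjusted p under 0.05 with PVP in limma, so the mixed test does not set these lists apart from other genes. It was not repeated over other splits or with the exon over intron area as a covariate. Of the 21 fixed genes tested, 0 passed in limma in any comparison between groups, with 5, 8 and 4 at an unadjusted p under 0.05 for citrate against control, PVP against control and PVP against citrate.

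**Figure D4:**
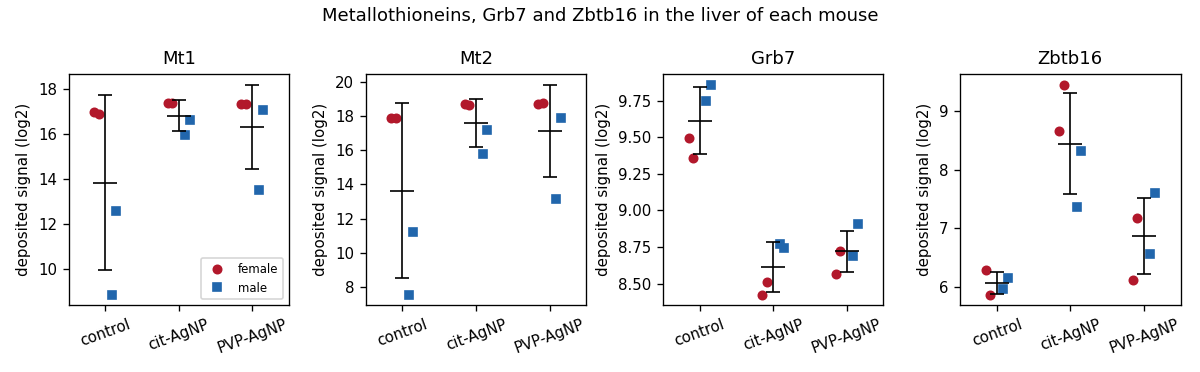
Log2 signal of Mt1, Mt2, Grb7 and Zbtb16 in each liver by group, with circles for females, squares for males and bars for mean ± SD (n = 4). Mt1 lies between 17.34 and 17.37 in the 4 exposed females and at 8.86 and 12.60 in the control males, and Grb7 is lower in each of the 8 exposed livers, 8.42 to 8.91, than in each control, 9.36 to 9.86.

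The direct comparison of PVP with citrate asked whether the coating alters the response. Heat shock genes were lower with PVP than with citrate as a set (camera adjusted p = 9.88e-06; adjusted p = 0.857 with an estimated correlation). Of 16, 7 were lower when adjusted over the list alone, while 0 passed over all genes in limma, with 10 at an unadjusted p under 0.05. Hsp90aa1 had a log2 difference of -1.19 (SE 0.20, adjusted p over all genes 0.212), Ahsa1 -0.66 (SE 0.11, adjusted p = 0.212) and Stip1 -1.12 (SE 0.23, adjusted p = 0.212). In Hsp90aa1 each PVP-treated liver lay below each citrate-treated liver, but over the list the livers overlapped. The median deviation from the control mean of the same sex was -0.24 in citrate replicate 2, below PVP replicate 4 at -0.22, and -0.01 to 0.06 in the other citrate-treated livers. Leaving out any single array gave 7 to 9 members, and 7 passed with the exon over intron area, lower on the PVP arrays, as a covariate. Fatty acid synthesis genes were lower with PVP, 20 of 21 below 0 (camera adjusted p = 1.29e-07). Over the list alone 8 passed, including Acacb, a mitochondrial acetyl-CoA carboxylase (-1.41, SE 0.32, adjusted p = 0.238), and the desaturase Fads2 (-0.95, SE 0.25, adjusted p = 0.247). Lpin1 had -3.31 (SE 0.86, adjusted p = 0.247). Oxidative phosphorylation genes were lower, 33 of 38 below 0 (camera adjusted p = 2.91e-08), and 9 passed over the list alone, such as Atp5b (-0.49, SE 0.13). Over all genes 0 members of either list passed in limma, with 8 and 19 at an unadjusted p under 0.05. Both set calls had an adjusted p of 0.857 with an estimated correlation. The fatty acid synthesis count was 2 without citrate replicate 1 or PVP replicate 1, 0 without citrate replicate 2 and 5 without citrate replicate 4. The oxidative phosphorylation count was 18 without PVP replicate 3 and 0 without control replicate 2 or 3, any of citrate replicates 1 to 4, or PVP replicate 1, 2 or 4. With the area as a covariate both counts were 0.

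Acute phase genes were higher with PVP than with citrate (camera adjusted p = 0.000132), with Saa2 at 5.29 (SE 1.34, adjusted p = 0.247) and Saa1 at 4.27 (SE 1.23, adjusted p = 0.258). The median deviation of this list in citrate replicate 1, 0.82, lay above those of PVP replicates 1, 3 and 4, 0.78, 0.19 and 0.38, and below that of PVP replicate 2, 1.57. Of the members, 0 of 27 passed over the list alone or over all genes in limma, with 11 at an unadjusted p under 0.05. Endothelial markers were lower (camera adjusted p = 0.000118), and 4 of 19 passed over the list alone, among them Oit3 (-0.95, SE 0.19, adjusted p = 0.212). Glutathione genes were lower (camera adjusted p = 0.0106), 3 over the list alone, including Gstm3 (-1.38, SE 0.27, adjusted p = 0.212). PVP replicate 3 stood apart in this list, since the median deviation of its members from the control mean of the same sex, -0.11, lay above those of the 4 citrate-treated livers, -0.35 to -0.16. PPAR-alpha targets (camera adjusted p = 0.0106) and cholesterol biosynthesis genes (camera adjusted p = 0.0427) were also lower, and the latter had 19 of 19 below 0; neither had a member past the list alone. Each of these calls had an adjusted p of 0.857 with an estimated correlation. The calls were lost without PVP replicate 2 for acute phase (0.0598) and without citrate replicate 2 or PVP replicate 1 or 2 for glutathione (0.104, 0.105 and 0.0598). They were lost without citrate replicate 2 or PVP replicate 1 for PPAR-alpha targets (0.104 and 0.406), and without citrate replicate 1 or PVP replicate 1, 3 or 4 for cholesterol (0.0778 to 0.573). Beside the lower exon over intron area of the PVP arrays, the endothelial count was 1 and the glutathione count 0 with the area as a covariate, and 0 and 1 without the 2 arrays of lowest area. The endothelial count was 1 without citrate replicate 1, 2 or 4 or PVP replicate 1 and 2 without control replicate 1, citrate replicate 3 or PVP replicate 4. The glutathione count was 0 without citrate replicate 2 or 4 or PVP replicate 2 and 1 without citrate replicate 1 or PVP replicate 4. Of the lists tested, 8 were called, against 15 without citrate replicate 4 and 16 without PVP replicate 3. Of 19985 genes, 0 passed in limma, with 2800 at an unadjusted p under 0.05, and the smallest adjusted p was 0.101, for Snord16a (0.79 higher with PVP, SE 0.09). Prox1, a hepatocyte transcription factor, had 1.25 (SE 0.18, adjusted p = 0.169), and Efna1, an ephrin, 2.06 (SE 0.38, adjusted p = 0.212).

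Both coatings shared Grb7 as a gene that fell, the 1 gene lower with citrate being among the 5 lower with PVP. At an adjusted p under 0.1, 7 genes were lower in both, Grb7, Bcar3, Camsap3, Tns2, Irak2, Gtf2ird1 and Atxn2, of 10 with citrate and 208 with PVP. The 1 gene higher with citrate at that threshold, the pseudogene Gm4910, was among the 64 higher with PVP. The number that shared control mice alone would give was not computed for these overlaps. The log2 fold changes of the coatings had a Pearson correlation of 0.505 across 19985 genes, which are not independent replicates. Both are measured against the same control mice, and simulated unchanged groups with shared controls gave a median of 0.566 and values at least as high in 56 of 100 simulations. With the controls split so that no control mouse was shared, the mean correlation was 0.139, from -0.136 to 0.390 over 4 splits. Simulated unchanged groups gave a median of 0.00975 for this mean, with values at least as high in 32 of 100 simulations and a central 95% from -0.632 to 0.594. The correlation with shared controls also lay within the central 95% of its simulations, -0.308 to 0.926.

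Females and males were compared across the groups. Of the 19985 genes, 435 differed at an adjusted p under 0.05, 186 higher and 249 lower in females, and 3055 at an unadjusted p under 0.05, against 8 and 4057 for PVP with control. Cyp2b9 and Cyp2b13, female-predominant cytochromes P450, were higher in females by 11.77 (SE 0.45) and 10.26 (SE 0.54) on the log2 scale, and Sult3a1, a sulfotransferase, by 9.09 (SE 0.82). Cyp4a12a, a male-specific fatty acid hydroxylase, had -10.96 (SE 0.38), Hsd3b5, a male-specific steroid dehydrogenase, -8.28 (SE 0.32), Elovl3, a fatty acid elongase, -6.83 (SE 0.36), and Cyp7b1, an oxysterol hydroxylase, -5.99 (SE 0.26). Of the 46 lists, 24 passed, 20 higher and 4 lower in females, and 2 of the 46 passed with an estimated correlation. The gene count was 266, 260, 245 and 264 without citrate replicate 1, 2, 3 or 4 and 271 without PVP replicate 4.

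Whether the response differed between the sexes was tested as the effect in females minus the effect in males, with 2 mice per sex and group. Of the genes tested, 0 passed for either coating in limma. At an unadjusted p under 0.05 there were 489 genes for citrate and 723 for PVP, where chance would give 999 on average. For citrate, Lrtm1 had a difference of 2.10 (SE 0.30, adjusted p = 0.521), with 1.40 in females and -0.69 in males. For PVP, Serpina3n, an acute phase protease inhibitor, had 2.95 (SE 0.49, adjusted p = 0.994), with 3.17 in females and 0.22 in males. Bcl6, a male-biased repressor, had -3.15 (SE 0.55, adjusted p = 0.994), and Pla2g15, a lysosomal phospholipase, 1.31 (SE 0.21, adjusted p = 0.994). Acute phase genes as a set responded more strongly in females to PVP (camera adjusted p = 1.73e-10), with 6 of 27 past the list alone, among them Serpina3n, Orm1 (1.27, SE 0.37) and Lcn2 (5.40, SE 1.39; 6.64 in females and 1.24 in males). Of the lists, 21 differed by sex for citrate and 16 for PVP; with an estimated correlation 0 did, with adjusted p-values of 0.676 to 0.755 for citrate and 0.617 to 0.71 for PVP. The citrate gene count was 2 without control replicate 3 and the PVP gene count 3 without control replicate 2. Within each sex 0 genes passed in limma. At an unadjusted p under 0.05 there were 797 for citrate in females and 1033 in males, and 2600 for PVP in females and 1601 in males. The average by chance was again 999, with a spread that was not computed.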

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

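The splits by sex balance and over the lists, and the tests of array quality, of single mice, of saturated metallothionein signals and of the low control male were chosen only after the results were seen; the lists whose splits were counted were picked after their counts of members were seen, and the other splits of the arrays were planned.

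A single value lay far from the other 3 of its group in 11 of 309 groups of values over 99 genes and 4 measures of the arrays; chance puts about 1 in 20 groups in this state. Anp32-ps had 12.36 in control replicate 2 and 12.13 in citrate replicate 4, C4b 14.73 in control replicate 4, Car3 19.59 in control replicate 1, Ehhadh 16.13 in control replicate 4 and Orm1 17.61 in control replicate 3. Mt1 had 13.52 and Mt2 13.13 in PVP replicate 3, a male. Ppfibp2 had 7.37 in PVP replicate 3, Uqcrc2 13.20 in citrate replicate 2 and Zfp395 7.31 in PVP replicate 1. Among probe sets with no gene symbol or several, which the gene counts leave out, 2 passed as higher with citrate when every probe set was tested.

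The response to the particles differed between the sexes in 21 lists for citrate and 16 for PVP with the preset correlation, and in 0 with an estimated correlation or with fry. For PVP, members that differed by sex when adjusted over their list alone numbered 6 for the acute phase, 2 for glucocorticoid-responsive genes, 2 for male-biased genes and 1 each for CAR and PXR targets, NF-kappaB targets and NRF2 targets. Lcn2 counts in both the acute phase and the glucocorticoid list. The other glucocorticoid member, Per1, went the opposite way (-1.77). The male-biased and NRF2 members were also below 0, and the acute phase, CAR and PXR, and NF-kappaB members above 0. Over all genes 0 differed for either coating in limma, with 489 and 723 at an unadjusted p under 0.05.

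Other splits of the same arrays were set against each result. For citrate against control, 1 of 35 splits gave as many genes as the real count of 1, and the highest other count was 0. Among the 18 of these splits with 2 females on each side, which are too few for a share under 0.05, the real split was also the 1 with a gene. For the lists 25 of 35 gave at least the real 9, with a highest other count of 22, so chance cannot be excluded. For PVP against control, 2 of 35 splits gave at least the real 8 genes, and the highest other count was 312, so chance cannot be excluded; that split put the 3 arrays of lowest exon over intron area among the 8, control replicate 2 and PVP replicates 1 and 4, on one side with PVP replicate 2 (mean areas 0.799 and 0.827), and 3 of the 4 arrays on that side were from females. This split was the real grouping with control replicate 2 and PVP replicate 3 exchanged, so it was not unrelated to the treatment. Left out singly, these arrays gave 14 and 61 genes. A count so far above the real one points to a structure of the arrays, and what it follows was not settled. Of the 35 splits, 3 had an area difference at least as large, and the others of these gave 0 genes. Among the 18 splits that balance sex, too few for a share under 0.05, the real split alone gave 8 genes, and the highest other count was 1. With the area as a covariate the real count was 2. For its lists 23 of 35 gave at least 13, with a highest other count of 22. For PVP against citrate, 35 of 35 gave at least the real 0 genes (highest other 11), and 29 of 35 at least the real 8 lists (highest other 25). For sex, 1 of 100 splits drawn gave the real 435 genes, with a highest other count of 3, so chance can be excluded.

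The heat shock genes lower with PVP numbered 8 of 16 adjusted over the list alone. Weak arrays or 1 outlying mouse are technical explanations, and the PVP-coated particles are a biological one. No group received PVP without silver, so the polymer and the coated particle cannot be told apart. For the heat shock list taken alone, 1 of 35 splits gave 8 members (highest other 1) and 1 of 35 gave 7 against citrate (highest other 3). The 18 splits that balance sex are too few for a share under 0.05 and cannot decide. Among them the real split alone gave as many in each comparison (highest other 1). The list was picked for its count, and in each comparison some list reached as many in 4 of 35 splits, the real one included. With that choice allowed for, chance cannot be excluded. Array quality as the whole cause is argued against by 6 members without the 2 arrays of lowest exon over intron area, and 1 outlying mouse by at least 6 members with any of the 4 PVP mice left out. A part played by quality stays open, as the area as a covariate left 5 members against control and 7 against citrate. A response to the PVP-coated particles may be a hypothesis for follow-up, found and tested on the same data.

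The acute phase genes higher with PVP, 14 of 27 adjusted over the list alone, were likewise picked for their count. For each list alone, 1 of 35 splits gave 14 (highest other 1) and 1 of 35 gave 10 glutathione members lower with PVP (highest other 3). The 18 splits that balance sex are too few for a share under 0.05 and cannot decide. Among them the real split alone gave as many in either case. Some list reached as many in 2 of 35 splits in either case, the real one included. The other was the split with 312 genes described above. With the choice of list allowed for, chance cannot be excluded. Array quality as the whole cause is argued against by 7 acute phase members without the 2 arrays of lowest exon over intron area. A leading part of 1 mouse could not be settled, because leaving out PVP replicate 2 left 2 members. An inflammatory response to PVP in some mice, stronger in the females, could be a biological explanation, and neither infection nor handling of single mice was tested.

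The metallothioneins had larger fold changes in males, with Mt1 at 5.56 in citrate-treated males and 0.44 in females and a difference of -5.12 (SE 1.80, limma adjusted p = 1). The sexes differed already in the controls. Citrate-treated females lay only 0.44 above control females for Mt1, while control males read 8.86 and 12.60, far below the exposed females. Saturated signals in females are a candidate explanation, since the 4 exposed females spanned 17.34 to 17.37 for Mt1 and the SD of 0.0107 lay at the 4.13th percentile of 218 genes of like level, whose median SD was 0.579; the ceiling of the table and Mt2 in PVP-treated females, 18.70 and 18.78, lay higher, so a limit near 17.37 would be one of the Mt1 probes. Low values of 1 control male stay open, because without control replicate 1 the Mt1 value in citrate-treated males was 3.69 (SE 1.16, 95% interval 0.974 to 6.404) against a single control male assumed to vary like the other groups, and the control males differed by 3.73. For Mt2 the value was 5.28 (SE 1.59, 95% interval 1.55 to 9.01), which goes against this explanation but rests on the same single control male. A true difference between the sexes stays open, as the design holds 2 mice per sex and group and control males themselves read 8.86 and 12.60.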

How the results depend on the processing

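Array quality as a covariate, the fit without the 2 arrays of lowest exon over intron area, protein-coding genes only, and counts of list members were tests chosen only after the results were seen. For 160 results of named genes, 2853 alternatives gave 2712 with the same direction and side of the threshold, 108 no longer past it, 23 newly past it and 10 reversed. Most of these results did not pass in the main fit, and staying short of the threshold counts as the same side. The 2712 therefore say little about the stability of the calls. Of 18 alternatives each, the call was kept in 15 for Snord16a, 7 for Anp32-ps, 6 for Grb7, 5 for Camsap3 and 2 for Gstk1 with PVP, and 7 for Grb7 with citrate. For counts and reversals the cause was not tested, save where fewer arrays or residual degrees of freedom, or another threshold, define the setting.

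The count for citrate, 1, was 4 with a stricter level filter, 3 with every probe set, 2 with median centring, 6 with quantile normalization (2 higher, 4 lower), 2 without a trend, 2 with robust moderation, 5 with array weights, 11 at an adjusted p under 0.1, 215 by unadjusted p and fold, 7 with a residual component, 5 with the area covariate and 11 among protein-coding genes; it was 0 without the sex term, with 2 groups, with 6 means and without the 2 arrays. Leaving out single arrays gave 0 to 6. The count for PVP, 8, was 4 with no filter, 85 with a stricter one, 5 with the mean of probe sets, 1 with every probe set, 52 without a trend, 3 with robust moderation, 37 with weights, 2 without the sex term, 0 with 2 groups, with 6 means and without the 2 arrays, 272 at an adjusted p under 0.1, 1037 by unadjusted p and fold, 1898 with a residual component, 2 with the area covariate and 89 among protein-coding genes, with 1 to 61 over single arrays left out. The residual component is orthogonal to the groups by construction, so fold changes stay and the spread shrinks. For PVP against citrate, 0, it was 2 with quantile normalization, 4 with weights, 1 with 6 means, 725 by unadjusted p and fold and 624 with a residual component.

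The count for sex, 435, was 860 with weights, 818 at an adjusted p under 0.1, 677 by unadjusted p and fold, 963 with a residual component and 929 with the area covariate, and 245 to 605 over single arrays left out. The differences by sex, 0, were 287 for citrate and 433 for PVP by unadjusted p and fold, and 0 to 2 and 0 to 3 over single arrays left out. The lists, 9, 13, 8 and 37 for citrate, PVP, PVP against citrate and both interactions, were each 0 with an estimated correlation, and 0, 2, 0 and 0 with fry. With no level filter they were 20 for PVP and 14 for PVP against citrate, which was 13 without the 2 arrays and 6 to 16 over single arrays left out. The correlation of the coatings, 0.505, was 0.139 with the controls split.

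Values near 0 reversed. Cdkn1a with PVP was 0.32 with the area covariate, 0.20 without the 2 arrays and -0.23 to 0.36 over single arrays left out (0.03 and 0.05 without control replicates 2 and 4). Lpin1 with PVP ran from -0.30 without PVP replicate 4 to 1.31, with -0.15 without control replicate 1. Between the coatings Mt1 ran from -1.37 to 0.0018 and Mt2 from -1.61 to 0.27 (without citrate replicate 4 for both), with Mt2 at 0.18 without PVP replicate 3.

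With the replicate number as a block the counts were 0 for citrate and PVP and 56 for sex; nothing in the labels pairs mice by number, and 4 of 12 same-number pairs were of unlike sex. The residuals of same-number pairs correlated at -0.440 to 0.234 (median -0.115, against 0.0464 for other numbers), and 0 of 12 arrays were closest to their own number in both other groups, so the numbers were not taken to pair the mice. Signal over background limits weak transcripts, and the ceiling limits the strongest: 106 tested genes stood at their own highest value on 8 or more arrays.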

Other observations

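The tests described here were planned, except that the single members were picked out after their values were seen.

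Some lists that did not pass as sets with PVP held members past their own adjustment. They were 1 higher and 2 lower of the targets of CAR and PXR, 2 lower each of iron handling, of autophagy and of fibrosis, 1 lower each of adipocyte markers and of nucleotide excision and mismatch repair, and 1 higher each of the clock and of the interferon response. Nfil3, a circadian and immune repressor, had 0.62 (SE 0.15, limma adjusted p over all genes 0.115). Mlh3, a mismatch repair protein, had -0.58 (SE 0.10, adjusted p = 0.0623). Hjv, the hemojuvelin co-receptor that drives hepcidin, had -1.13 (SE 0.17, adjusted p = 0.0566). Car3, a carbonic anhydrase of adipocytes and hepatocytes, had -1.16 (SE 0.32, adjusted p = 0.133), and of the CAR and PXR targets, of which 20 of 28 lay below 0, the cytochrome P450 genes Cyp3a13 and Cyp2c55 had 1.15 (SE 0.31, adjusted p = 0.126) and -0.89 (SE 0.22, adjusted p = 0.117), while Gstm3 also fell. These lists had iron handling at a camera adjusted p of 0.159, targets of CAR and PXR at 0.319, and nucleotide excision and mismatch repair at 0.0707.

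Hepatocyte zonation and sex-biased genes did not pass as sets with PVP. Pericentral markers had a median log2 fold change of -0.19 and periportal markers -0.44, with a camera adjusted p of 0.187 for both. Female-biased genes had a median of -0.37 (camera adjusted p = 0.176) and male-biased genes -0.21 (camera adjusted p = 0.809). Interferon response genes had a median of -0.0024 with PVP, opposite in sign to the test (camera adjusted p = 0.507), and -0.07 with citrate (camera adjusted p = 0.197).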
